A study of Mus musculus with 8 samples.

How the data were processed

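Gene expression was measured in whole lung RNA of mice given mepenzolate, a muscarinic receptor blocker, or vehicle through the trachea under chloral hydrate (500 mg/kg). Lungs were taken 7 h or 25 h after dosing. The 4 groups held 2 arrays each, 8 arrays in all, and each array's group and replicate number came from its title. Nothing in the labels says that the 2 arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. The 2 vehicle arrays at 7 h differed by 5.45 log2 units in H2-Ea and by 4.16 in Ang5.

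The values deposited by the authors were log2 expression levels of 34760 probes on Affymetrix mouse gene arrays, summarised with RMA (robust multi-array average) per the submitters' processing notes. The RMA version was not given in the sources used here. RMA subtracts background, equalises the distribution of intensities between arrays and combines the probes of a transcript, which compresses differences of dim genes. The values ran from 2.00 to 13.98, and the array medians from 6.70 to 6.77. Arrays have no read depth, so their number limits the precision.

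Of the probes, 21640 had 1 gene symbol in the platform annotation, 1321 had several and 11799 were unnamed here. By Entrez identifier 21553 of the first class matched the RefSeq gene table of GRCm38.p6, 87 did not, and 0 symbols changed. Only probes with 1 symbol were named. Among several probes of a gene, as for 954 genes, the one with the highest mean over the 8 arrays was used, which gave 19937 genes. Genes with a mean at or above the 25th percentile of these (log2 5.93) were tested, 14953 in number.

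The deposited values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 8 arrays sharing 1 estimate of spread (4 residual degrees of freedom, 4.09 prior degrees of freedom). The comparisons were mepenzolate against vehicle at 25 h, at 7 h and averaged over both times, the difference of that effect between the times, and 25 h against 7 h in vehicle lungs. These share arrays, so no overlap or correlation of calls between them was computed. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors of log2 differences are moderated standard errors. An exact permutation test of 1 gene could not fall below 0.333 with 2 arrays against 2, or below 0.0286 with 4 against 4. Values were read with the data.table package, version 1.17.8.

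Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. There were 52 lists, 26 of pathways or complexes and 26 of cell type markers, with 1158 entries, of which 1052 matched a probe with 1 symbol and 959 were tested. Lists on oxidative stress enzymes, histone deacetylases and muscarinic receptors were chosen with general knowledge of the study's theme. Some genes stand in several lists, such as Sult1a1 (glucocorticoid response and cytochrome P450) and Ltf (club cells and neutrophils). Calls of lists that share genes are not independent. For called lists, members were also counted after adjustment over the list alone. Camera had picked these lists from the same data, and the counts were not corrected over lists or comparisons. They describe a list and give its call no separate support. Alternatives for the lists were camera with an estimated correlation, fry, fgsea 1.28.0, no filter, quantile normalization and a replicate block. For genes they were a replicate block, no filter, a stricter filter, quantile normalization, median centring, an intensity trend with robust estimation, array weights, the mean of a gene's probes and fits on the compared groups only. Each array was also left out in turn, when the lone array of a group is assumed to vary like the others. Groups, comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined.

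The genes named for the 25 h and 7 h comparisons were the 10 largest passing differences in each direction without overlap of arrays. The limit was 6 and 6 for the vehicle time course and for both times, and 4 and 4 for the difference between times. Places left empty went to the smallest unadjusted p-values, and such genes are said not to have passed. Of each list called, the 4 members with the largest moderated t in its direction could be named, along with list members that passed. In addition, 18 genes of inflammation, redox control and muscarinic signalling were fixed by name.

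The procedure was tested on simulated data for the 25 h comparison over 14953 genes. At each size of change 50 genes were altered. The procedure recovered 64% of genes changed by log2 0.5, 96% of those changed by 1 and 100% of those changed by 2 or 3. Of the 192 calls 12 were unchanged genes. The noise was normal, with each gene's moderated spread, and outlying arrays or shared array differences were not simulated. Where fewer genes change, the Benjamini-Hochberg cutoff is also stricter. Recovery in the real data may therefore be lower, and a comparison without calls does not exclude changes of these sizes. Camera recovered a glutathione S-transferase list shifted by 0.2 and called 0 other lists. The simulated genes varied independently of each other, so this could not show how often correlated genes give false list calls. A further 13120 probes without a single symbol were tested on their own where bright enough (6267 probes). Limma called 0 of them in any of the 5 comparisons, with 372, 167, 288, 206 and 292 at an unadjusted p under 0.05 in the order above. The other alternatives were not run on them.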

Results

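Lung expression profiles were compared between mice given mepenzolate and mice given vehicle, at 7 h and 25 h after dosing, with 2 arrays in each of the 4 groups. The study asked how mepenzolate lowers inflammatory responses and oxidative stress in the lung, and looked at gene sets at 25 h. The 4 pairs of replicate arrays correlated at r = 0.988 to 0.993 (median 0.991) across probes, which are not independent replicates, and the 24 pairs of arrays from different groups also at 0.988 to 0.993 (median 0.991). The lowest r among all pairs was that of the 2 mepenzolate arrays at 7 h. The SD of the log2 differences between replicates was lowest in the vehicle group at 25 h (0.153) and highest in the mepenzolate group at 7 h (0.235). All differences below are log2 values with their standard errors, from 2 arrays per group unless stated. Over all genes tested the median difference, mepenzolate minus vehicle, was -0.023 at 25 h and -0.013 at 7 h. Counts of higher and lower list members therefore do not start from an even split. Median centring was not run for the lists.

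At 25 h, genes of the cytosolic ribosome stood higher in mepenzolate lungs than in vehicle lungs, with 26 of 29 members higher and a mean log2 difference of 0.15. Among them were Rps13 (0.61 ± 0.14), Rpl5 (0.39 ± 0.14), Rpl38 (0.60 ± 0.23) and Rpl30 (0.22 ± 0.08). Mesothelial markers were also higher as a list (7 of 10 members, mean 0.19), including the uroplakins Upk3b (0.41 ± 0.09) and Upk1b (0.41 ± 0.18) and mesothelin, Msln (0.45 ± 0.13). These lists had camera adjusted p = 5.08e-09 and 0.00345, and each had adjusted p = 0.883 with an estimated correlation. Adjusted over the list alone, 0 ribosomal and 2 mesothelial genes passed limma. Without the first vehicle array Rpl5 stood at 0.21, Rpl38 at 0.23 and Upk1b at 0.23. Rpl38 stood at 0.40 without the second mepenzolate array and 0.97 without the second vehicle array, and Upk1b at 0.26 without the first mepenzolate array.

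Enzymes that detoxify foreign or oxidised compounds were higher at 25 h as well. Of 20 glutathione S-transferase genes 15 were higher (mean 0.09, camera adjusted p = 0.00441), and adjusted p = 0.883 with an estimated correlation. The leading members were Gsto1 (0.31 ± 0.09), Mgst2 (0.39 ± 0.12), Gsta4 (0.40 ± 0.14) and Gsta3 (0.31 ± 0.16). Of 20 cytochrome P450 and xenobiotic metabolism genes 14 were higher (mean 0.11, camera adjusted p = 0.00441), and adjusted p = 0.883 with an estimated correlation. Cyp3a13 stood at 0.63 ± 0.14 and the carboxylesterase Ces1g at 0.45 ± 0.13. Targets of NRF2, the main transcription factor of the antioxidant response, were higher in 17 of 25 cases (mean 0.05, camera adjusted p = 0.0422), with Ephx1, microsomal epoxide hydrolase, at 0.30 ± 0.08. For the NRF2 list adjusted p = 0.883 with an estimated correlation. Limma passed 0 glutathione S-transferase, 1 cytochrome P450 list and 0 NRF2 list genes when adjusted over the list alone. Gsta3 overlapped between the groups and stood at 0.038 without the second mepenzolate array and 0.59 without the first. Mgst2 stood at 0.25 without the second mepenzolate array, Ces1g at 0.30 without the first and Gsta4 at 0.24 without the second vehicle array.

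Respiratory chain genes were higher in 19 of 33 cases (mean 0.06, camera adjusted p = 0.00667), with Cox7b of complex IV at 0.36 ± 0.11 and Ndufs1 of complex I at 0.26 ± 0.08. Proteasome genes were higher in 24 of 31 cases (mean 0.04, adjusted p = 0.0155), heat shock genes in 12 of 18 (mean 0.05, adjusted p = 0.0287) and thymocyte markers in 7 of 9 (mean 0.12, adjusted p = 0.0311). Each of these 4 lists had adjusted p = 0.883 with an estimated correlation. Endothelial markers were lower in 19 of 23 cases (mean -0.09, adjusted p = 0.0187), led by the transcription factor Sox18 (-0.45 ± 0.08) and the diaphragm protein gene Plvap (-0.28 ± 0.12). Proliferation genes were lower in 27 of 32 cases (mean -0.09, adjusted p = 0.0470), led by the mitotic kinase Plk1 (-0.30 ± 0.13) and Uhrf1 (-0.32 ± 0.17). The endothelial and proliferation lists also had adjusted p = 0.883 with an estimated correlation. By limma, 1 thymocyte gene, 1 endothelial gene and 0 genes of the other 4 lists passed when adjusted over the list alone. Without the first mepenzolate array Plvap stood at -0.099 and Plk1 at -0.11, and without the second at -0.46 and -0.48, with Cox7b at 0.21. Uhrf1 stood at -0.092 without the first and -0.55 without the second vehicle array.

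**Figure D1:**
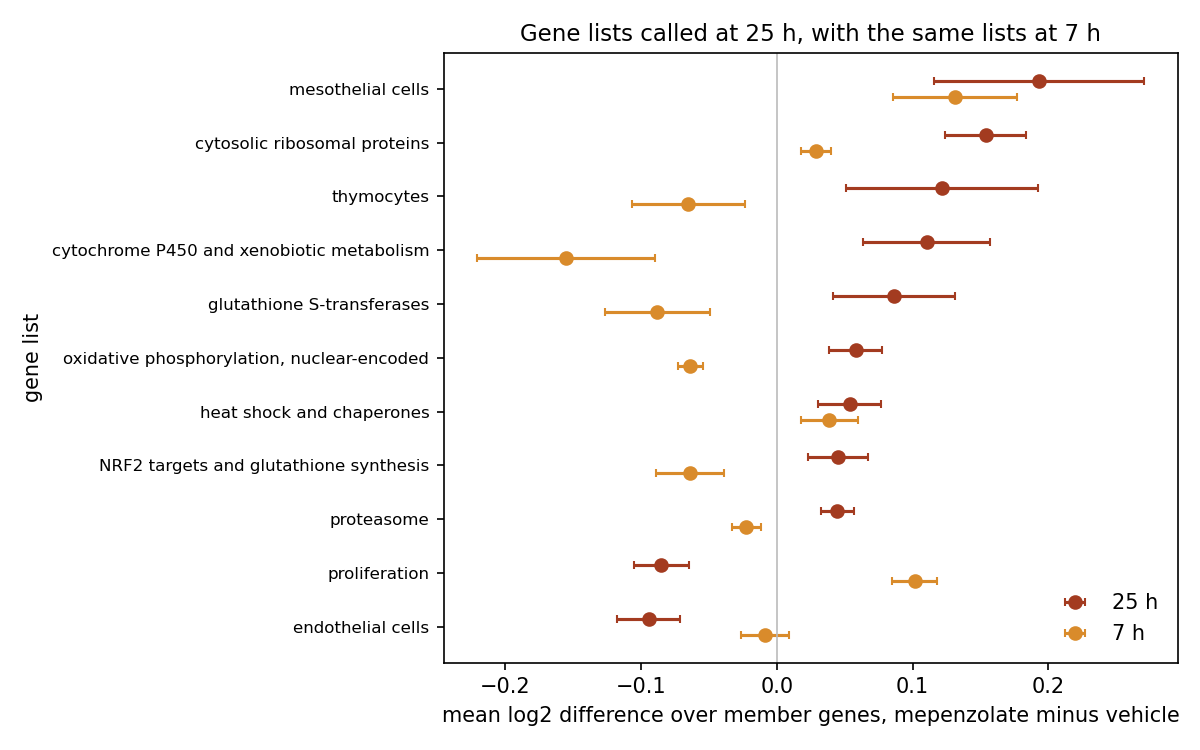
Mean log2 difference, mepenzolate minus vehicle, over the member genes of the 11 lists called at 25 h (dark red points), with the same lists at 7 h (orange points) and bars of 1 standard error over member genes. Proliferation genes averaged -0.09 at 25 h and 0.10 at 7 h, and glutathione S-transferases 0.09 and -0.09.

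Camera called 11 of the 52 lists at 25 h, 9 higher and 2 lower, against 0 with an estimated correlation, 0 with fry and 10 with fgsea. At an unadjusted p under 0.05 an estimated correlation gave 1 list and fry 2. Camera at the same preset correlation also called 12 of 52 lists between replicate numbers 1 and 2, where no treatment differed. Leaving out single arrays kept the mesothelial call each time and ended every other call at least once. Without the second mepenzolate array the ribosomal (mean 0.06), glutathione S-transferase (0.08), cytochrome P450 (0.13), NRF2 (0.04), proteasome (0.04) and thymocyte (0.09) calls ended, and the heat shock mean was 0.10. Without the first mepenzolate array the endothelial (-0.08), heat shock (0.0044) and proliferation (-0.04) calls ended, and the ribosomal mean was 0.25. Without the second vehicle array the glutathione S-transferase (0.04), cytochrome P450 (0.06), NRF2 (0.0042), proteasome (0.04), endothelial (-0.05) and heat shock (0.05) calls ended, while proliferation stood at -0.15 and thymocytes at 0.20. Without the first vehicle array the respiratory chain (0.04), thymocyte (0.05) and proliferation (-0.02) calls ended, while glutathione S-transferases stood at 0.13 and NRF2 targets at 0.09. Quantile normalization ended the respiratory chain, proteasome, heat shock, NRF2 and proliferation calls, and fgsea those of thymocytes and proliferation, as did dropping the filter. The number of lists called was 19 without the first and 7 without the second vehicle array.

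No single gene passed limma at 25 h. It called 0 of 14953 genes (smallest adjusted p = 0.979), with 599 at an unadjusted p under 0.05, 230 higher and 369 lower. Chance would give 748 such genes. The genes with the smallest p that stood higher in both mepenzolate arrays were Abcg3 (0.66 ± 0.09), a transporter gene, Nudt21 (0.50 ± 0.08), a component of the mRNA cleavage machinery, and Cd3g (0.57 ± 0.10), a chain of the T cell receptor complex. Others were Pon1, Scgb1c1, Padi4, Cyp3a13, Odc1, Rps13 and Upk3b, at 0.41 to 0.94. Without the first mepenzolate array Scgb1c1 stood at 0.52. The lower genes were led by the interferon-inducible GTPase Gbp4 (-0.96 ± 0.16), Slc26a11 (-0.43 ± 0.08), the matrix protein gene Spon2 (-0.62 ± 0.11), Sox18, Grin2c (-0.50 ± 0.10) and the protein C receptor Procr (-0.55 ± 0.11). Sdhaf4, Gpr141b, Cdh13 and the somatostatin receptor Sstr4 stood at -0.69 to -0.39. Groups did not overlap for 36.6% of genes, against 33.3% by chance. Leaving out the second vehicle array gave 1 call, Gdpd3 (-3.13), and a replicate block gave 1 call, Snord73b (0.97), both named after their values were seen.

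The genes fixed in advance for inflammation and redox control showed small differences at 25 h. Of 18 genes 16 were bright enough to test, 0 passed limma and 1 had an unadjusted p under 0.05, the muscarinic receptor gene Chrm2 (0.35 ± 0.12). Chrm1 stood at -0.03 ± 0.10 and Chrm3 at 0.17 ± 0.21. The histone deacetylase gene Hdac2 stood at 0.12 ± 0.09, superoxide dismutases Sod1 and Sod3 at 0.01 ± 0.09 and -0.02 ± 0.11, and the NADPH oxidase subunits Cybb and Ncf1 at -0.01 ± 0.12 and -0.12 ± 0.08. Sod1 turned negative under quantile normalization (-0.013) and Sod3, Cybb and Eln (elastin) turned positive under median centring (0.0033, 0.016 and 0.020). Tnf stood at 0.03 ± 0.15, Cxcl1 at -0.03 ± 0.09, Ccl2 at -0.12 ± 0.15, Mmp12 at -0.05 ± 0.11, Nfe2l2, which encodes NRF2, at 0.04 ± 0.07 and Nfkbia at 0.05 ± 0.09. Il6 (-0.17 ± 0.09) and Cxcl2 (-0.07 ± 0.16) were below the filter level. With 1 array left out, 7 of the 16 tested genes changed sign and 15 moved by over 1.5 times at least once. Hdac2 ranged from 0.047 to 0.20 and Chrm3 from 0.044 to 0.29, without the first and the second vehicle array. The cytokine and chemokine list (11 of 27 members higher, camera adjusted p = 0.563), the NF-kappaB list (5 of 22 higher, 0.496), NADPH oxidase subunits (2 of 12 higher, 0.563) and histone deacetylases (4 of 18 higher, 0.361) were not called.

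At 7 h the comparison asked what mepenzolate did earlier after dosing. Genes that glucocorticoids induce were lower in mepenzolate lungs, with 16 of 19 members lower and a mean log2 difference of -0.28. They included Zbtb16 (-1.16 ± 0.22), a transcription factor gene, Angptl4 (-0.60 ± 0.10), an inhibitor of lipoprotein lipase, Fkbp5 (-0.51 ± 0.15), a co-chaperone of the glucocorticoid receptor, and Ddit4 (-0.43 ± 0.09), which restrains mTOR signalling. The list had camera adjusted p = 1.09e-09, and adjusted p = 0.265 with an estimated correlation. Adjusted over the list alone, 6 members were lower and 1 higher. Fkbp5 stood at -0.34 without the second vehicle array. Array by array the list score was 0.40 and 0.38 in vehicle lungs and 0.09 and 0.12 in mepenzolate lungs, relative to the mean of all 8 arrays.

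Platelet and megakaryocyte genes were lower in all 13 tested members at 7 h (mean -0.29), among them Itga2b (-0.55 ± 0.10), the platelet integrin chain, Gp9 (-0.57 ± 0.12), part of the von Willebrand factor receptor, Tubb1 (-0.50 ± 0.11) and Alox12 (-0.45 ± 0.14). This list had camera adjusted p = 1.13e-09, and adjusted p = 0.265 with an estimated correlation. Proliferation genes were higher in 29 of 32 cases (mean 0.10), led by Mki67 (0.35 ± 0.09) and Ube2c (0.23 ± 0.10), with camera adjusted p = 6.58e-08, and adjusted p = 0.406 with an estimated correlation. Inflammatory cytokine and chemokine genes were higher in 18 of 27 cases (mean 0.16), with Cxcl10 at 0.46 ± 0.15, Ccl2 at 0.37 ± 0.15, Ccl7 at 0.22 ± 0.10 and Cxcl9 at 1.21 ± 0.65. That list had camera adjusted p = 0.000273, and adjusted p = 0.265 with an estimated correlation. Adjusted over the list alone, 4 platelet genes, 0 proliferation genes and 0 cytokine genes passed limma, against 0 genes adjusted over all genes tested. Without the first mepenzolate array the proliferation mean was 0.06. The cytokine examples were higher on the second mepenzolate array. Without it Cxcl9 stood at 0.045, Cxcl10 at 0.21, Ccl2 at 0.18, Ccl7 at 0.13 and Alox12 at -0.22, and without the first Cxcl9 stood at 2.38, Cxcl10 at 0.70, Ccl2 at 0.56 and Alox12 at -0.69. Ccl2 stood at 0.20 without the first and Ccl7 at 0.12 without the second vehicle array.

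Conducting airway genes were lower as lists at 7 h. Relative to the mean of all arrays, the club score was 0.20 and 0.21 in vehicle lungs and 0.02 and -0.52 on the mepenzolate arrays. The ciliated score was low on the second mepenzolate array alone (-0.39, against 0.12 on the first). The club and secretory cell list was lower in 17 of 20 cases (mean -0.45), with the lactoferrin gene Ltf at -1.40 ± 0.42, the trefoil peptide Tff2 at -1.24 ± 0.29, Lypd2 at -0.67 ± 0.12 and Scgb3a1 at -0.51 ± 0.13. It had camera adjusted p = 6.51e-09, and adjusted p = 0.371 with an estimated correlation. Its mean was -0.18 without the second mepenzolate array and -0.72 without the first. Ciliated cell genes were lower in 25 of 26 cases (mean -0.18), with Foxj1, the regulator of motile cilia, at -0.22 ± 0.10. That list had camera adjusted p = 0.000273, and adjusted p = 0.608 with an estimated correlation. Without the second mepenzolate array the ciliated mean turned to 0.08 and was not called. It was -0.43 without the first, and the call ended without the second vehicle array (-0.14). The same second mepenzolate array held the high liver genes. The liver list was higher in 6 of 7 cases (mean 0.32, camera adjusted p = 0.00741), led by Ahsg (0.63 ± 0.15) and albumin, Alb (1.42 ± 0.68), and adjusted p = 0.417 with an estimated correlation. The liver mean was 0.03 without that array and 0.61 without the first mepenzolate array, and the call ended without the first vehicle array (0.23). Limma passed 3 club cell genes, 0 ciliated genes and 1 liver gene when adjusted over the list alone. Without the second mepenzolate array Ltf stood at -0.63, Foxj1 at -0.094, Alb at 0.078 and Ahsg at 0.37, and without the first Ltf stood at -2.17, Foxj1 at -0.36 and Alb at 2.76.

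The cytochrome P450 and glutathione S-transferase lists, higher at 25 h, were lower at 7 h as lists, though Cyp3a13 stood at 0.17 ± 0.14 and Gsta4 at -0.027 ± 0.14 at 7 h. These 2 turned to -0.058 and 0.14 without the second mepenzolate array, and stood at 0.39 and -0.19 without the first. Cytochrome P450 and xenobiotic genes were lower in 15 of 20 cases (mean -0.16), with Ces1f at -0.53 ± 0.11, Aldh3a1 at -0.70 ± 0.17 and Ces1g at -0.42 ± 0.13. Their camera adjusted p was 0.00069, and adjusted p = 0.371 with an estimated correlation. Glutathione S-transferases were lower in 17 of 20 cases (mean -0.09), with Mgst2 at -0.28 ± 0.12 and Gstt1 at -0.54 ± 0.30. Their camera adjusted p was 0.0231, and adjusted p = 0.512 with an estimated correlation. Without the second mepenzolate array, which had low airway and high liver genes, both calls ended (cytochrome P450 -0.10, glutathione S-transferases -0.02). Both also ended without the second vehicle array (-0.12 and -0.07), and glutathione S-transferases stood at -0.16 without the first mepenzolate array. By limma, 2 cytochrome P450 list genes and 0 glutathione S-transferase genes passed when adjusted over the list alone. Gstt1 stood at -0.21 without the second and -0.86 without the first mepenzolate array, and at -0.32 without the first vehicle array. Cardiac muscle genes, a sign of heart or pulmonary vein tissue in a lung sample, were lower in 18 of 21 cases (mean -0.27), with myoglobin, Mb, at -0.62 ± 0.16 and Pln at -0.68 ± 0.24. Their camera adjusted p was 1.96e-06, and adjusted p = 0.551 with an estimated correlation. That call ended without the first mepenzolate array (-0.16). Adjusted over the list alone, 0 cardiac genes passed limma.

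Oxidant and antioxidant lists were also called at 7 h. NADPH oxidase subunits were higher in 8 of 12 cases (mean 0.066, camera adjusted p = 0.0381), and adjusted p = 0.371 with an estimated correlation. Targets of NRF2 were lower in 18 of 25 cases (mean -0.064, camera adjusted p = 0.0379), and adjusted p = 0.608 with an estimated correlation. In neither list did a gene pass limma (0 adjusted over the list alone). The NADPH oxidase call ended without the first (0.042) or the second (0.090) mepenzolate array and without the first vehicle array (0.025), and the mean was 0.11 without the second vehicle array. The NRF2 mean turned to 0.0021, no longer called, without the second mepenzolate array, and the call ended without the first (-0.052) or the second (-0.076) vehicle array. The mean was -0.13 without the first mepenzolate array. Both calls also ended without either mepenzolate array at 25 h, with the same means.

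**Figure D2:**
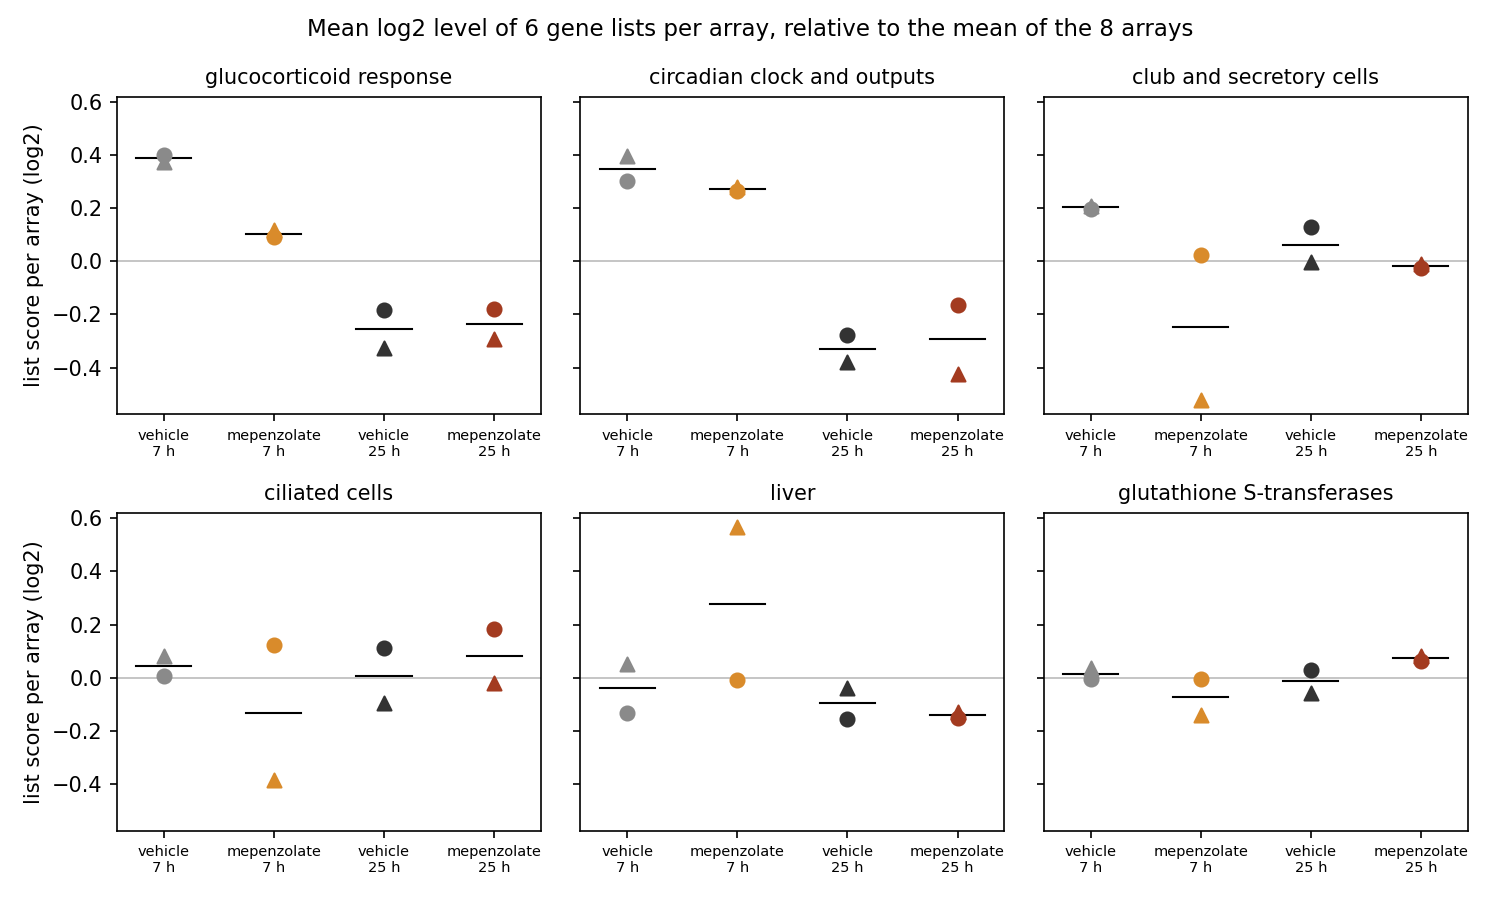
Mean log2 level of 6 gene lists on each of the 8 arrays, relative to the mean of all arrays (circles, replicate 1; triangles, replicate 2; bars, group means). The glucocorticoid score is 0.40 and 0.38 in vehicle lungs and 0.09 and 0.12 in mepenzolate lungs at 7 h, and the second mepenzolate array at 7 h stands apart in the club (-0.52), ciliated (-0.39) and liver (0.57) scores.

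Camera called 26 of 52 lists at 7 h, 13 in each direction, against 0 with an estimated correlation (smallest adjusted p = 0.265), 0 with fry (0.350) and 20 with fgsea. At an unadjusted p under 0.05 an estimated correlation and fry each gave 5 lists. The glucocorticoid, platelet, club, proliferation and cytokine calls held with each array left out, and the other 21 calls ended at least once. The number of lists called was 17 without the first and 10 without the second mepenzolate array, and 15 without the second vehicle array.

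Limma called 0 genes at 7 h (smallest adjusted p = 0.966), with 357 at an unadjusted p under 0.05, 111 higher and 246 lower, against 748 by chance. Groups did not overlap for 23.7% of genes, against 33.3% by chance. It called 2 genes without the first mepenzolate array, Alb (2.76) and the airway secretory protein gene Bpifa1 (-2.40), and 1 without the second, Atrn (-1.64). Bpifa1 and Atrn were named after their values were seen. Genes with the smallest p that stood higher in both mepenzolate arrays were the ribonuclease Rnase1 (0.75 ± 0.11), Rnf225 (0.54 ± 0.08), Scrg1 (1.23 ± 0.25), Abcg3 (0.42 ± 0.09), the chloride channel gene Cftr (0.69 ± 0.15) and the immunoglobulin joining chain, Jchain (0.57 ± 0.13). Fbxo44, Rarres1, Ahsg and Zfp617 stood at 0.56 to 0.79. The lower genes, besides those named in lists above, were Rtn1 (-0.51 ± 0.08), Nt5dc3 (-0.50 ± 0.08), Padi4 (-1.09 ± 0.20), which encodes a histone citrullinating enzyme of neutrophils, and Cd300lg (-0.86 ± 0.17). The genes fixed in advance ranged from -0.24 to 0.37, and 0 of 16 passed limma. With 1 array left out, 12 of the 16 changed sign and 15 moved by over 1.5 times at least once. Of them 2 had an unadjusted p under 0.05, Nfkbia (-0.24 ± 0.09), the inhibitor of NF-kappaB, and Ccl2. Nfkbia stood at -0.15 without the first vehicle array. Cftr stood at 0.45 without the first mepenzolate array, Ahsg at 0.37 without the second, and Cd300lg at -0.57 without the first vehicle array.

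Averaged over both times, with 4 arrays against 4, ribosomal genes stood higher under mepenzolate in 26 of 29 cases (mean 0.09, camera adjusted p = 1.69e-08), and adjusted p = 0.767 with an estimated correlation. Mesothelial genes were higher in 7 of 10 cases (mean 0.16, camera adjusted p = 4.13e-05), with Msln at 0.39 ± 0.10, and adjusted p = 0.568 with an estimated correlation. Platelet genes were lower in 12 of 13 cases (mean -0.14, camera adjusted p = 0.000363), and adjusted p = 0.767 with an estimated correlation. The platelet mean was -0.29 at 7 h and -0.0010 at 25 h, where 7 of 13 members were higher and the list was not called (camera adjusted p = 0.666). The 25 h mean was -0.087 without the first and 0.085 without the second mepenzolate array. Limma passed 0 ribosomal, 2 mesothelial and 2 platelet genes when adjusted over the list alone. These 3 calls held with each array left out, while the other 6 of 9 ended at least once. The ribosomal mean was 0.14 without the first and 0.04 without the second mepenzolate array at 25 h. The number of lists called was 14 without the first vehicle array at 25 h and 16 without the second vehicle array at 7 h. An estimated correlation gave 0 lists, fry 0 and fgsea 7, and at an unadjusted p under 0.05 they gave 2 with an estimated correlation and 3 with fry.

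Single genes over both times were led by Abcg3 (0.54 ± 0.06, adjusted p = 0.388) and the ubiquitin ligase gene Rnf225 (0.43 ± 0.06, adjusted p = 0.472), which did not pass limma. Cd300lg stood at -0.73 ± 0.12 (adjusted p = 0.874). Rnase1 (0.44 ± 0.08), Zfp617 (0.46 ± 0.09), Scrg1 (0.83 ± 0.17) and Anp32-ps (0.39 ± 0.09) stood higher, and Pop4, Clmn, Cst7, Slc52a3 and Clba1 stood at -0.43 to -0.26. Limma called 0 genes, with 563 at an unadjusted p under 0.05, 175 higher and 388 lower. Groups did not overlap for 2.41% of genes, against 2.86% by chance. With 1 array left out it called Alb (1.53) and Bpifa1 (-1.12) without the first mepenzolate array at 7 h, and Atrn (-0.87) and Slc37a1 (1.12) without the second. It called Gdpd3 (-1.49) without the second vehicle array at 25 h and Cd300lg (-0.88) without the second vehicle array at 7 h.

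The difference of the mepenzolate effect between 25 h and 7 h was tested directly. Glucocorticoid genes differed by 0.30 (25 h minus 7 h, mean log2), with Zbtb16 at 1.42 ± 0.32 and Tsc22d3 at 0.53 ± 0.15, and platelet genes by 0.29, with Itga2b at 0.69 ± 0.14. Cytochrome P450 genes differed by 0.27, with Sult1d1 at 1.41 ± 0.40, glutathione S-transferases by 0.17, with Mgst2 at 0.67 ± 0.17, and respiratory chain genes by 0.12. Club cell genes differed by 0.37 and proliferation genes by -0.19, with Mki67 at -0.49 ± 0.13. These 7 lists had camera adjusted p from 2.75e-07 to 4.7e-05, and each had adjusted p = 0.396 with an estimated correlation. They held with each array left out, though the club mean was 0.65 without the first and 0.10 without the second mepenzolate array at 7 h. Glutathione S-transferases stood at 0.11 without that second array, and proliferation at -0.12 without the first vehicle array at 25 h. By limma, 1 glucocorticoid, 1 platelet, 1 club cell and 4 cytochrome P450 list genes and 0 genes of the other 3 lists passed when adjusted over the list alone.

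Camera called 21 lists for this difference, 14 higher and 7 lower, against 0 with an estimated correlation, 0 with fry (smallest adjusted p = 0.503) and 17 with fgsea. At an unadjusted p under 0.05 an estimated correlation gave 5 lists and fry 3, and 13 lists were called without the second vehicle array at 25 h. Limma called 0 genes, with 400 at an unadjusted p under 0.05. It called Alb (-2.46) and Bpifa1 (2.56) without the first mepenzolate array at 7 h, Atrn (1.55) without the second, and Gdpd3 (-3.28) without the second vehicle array at 25 h. The smallest p-values belonged to Padi4 (2.04 ± 0.28), Rtn1 (0.71 ± 0.12), Cd3g (0.78 ± 0.15) and Grid1 (0.94 ± 0.18) among positive differences. Among negative ones they belonged to Sdhaf4 (-0.60 ± 0.11), Gbp4 (-1.06 ± 0.22), Spon2 (-0.72 ± 0.16) and Fbxo44 (-1.15 ± 0.25).

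In vehicle lungs, clock genes changed between 7 h and 25 h. The design does not separate time after dosing from time of day or from recovery after anaesthesia and tracheal dosing. That limit holds for every gene and list of the vehicle time course. The clock activator Arntl rose by 1.46 ± 0.13 (limma adjusted p = 0.0158), while its repressors Per1, Per2 and Per3 fell by 1.81 ± 0.21, 1.39 ± 0.12 and 1.39 ± 0.15 (adjusted p = 0.0287, 0.0158 and 0.0255). The clock-controlled transcription factors Hlf (-1.35 ± 0.16), Bhlhe41 (-1.20 ± 0.11) and Tef (-0.77 ± 0.08), the deubiquitinase Usp2 (-0.96 ± 0.11) and Tspan4 (-0.94 ± 0.09) fell too. Zbtb16 (-2.10 ± 0.22) and Tsc22d3 (-1.07 ± 0.10), which encodes a glucocorticoid-induced leucine zipper protein, also fell. Spon2 (1.42 ± 0.11) and the vasodilator peptide gene Adm (1.06 ± 0.13) rose. These 13 genes, 3 higher and 10 lower, were all that passed limma, with 859 at an unadjusted p under 0.05. Ppp1r3c (0.64 ± 0.10), Cd52 (0.49 ± 0.08) and Orai2 (0.51 ± 0.08) did not pass. Groups did not overlap for 43.1% of genes, against 33.3% by chance. Leaving out a vehicle array, which leaves 1 alone in its group, gave 1 call without the first (Per1, -2.18) or the second array at 25 h (Gdpd3, 3.07) and 0 without the first or the second at 7 h, and quantile normalization gave 7. Quantile normalization ended the calls of Adm, Hlf, Per1, Per3, Usp2 and Zbtb16 (adjusted p = 0.0523 to 0.0760), and a fit on the vehicle arrays alone those of Hlf, Per1, Per3, Tef, Tspan4 and Zbtb16 (0.0565 to 0.131). The call of Per1 also ended without either mepenzolate array at 25 h (adjusted p = 0.0877), and those of Per1 and Hlf without either at 7 h (0.0535), with the same log2 differences. Array weights gave 55 calls, an intensity trend 33 and median centring 19.

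**Figure D3:**
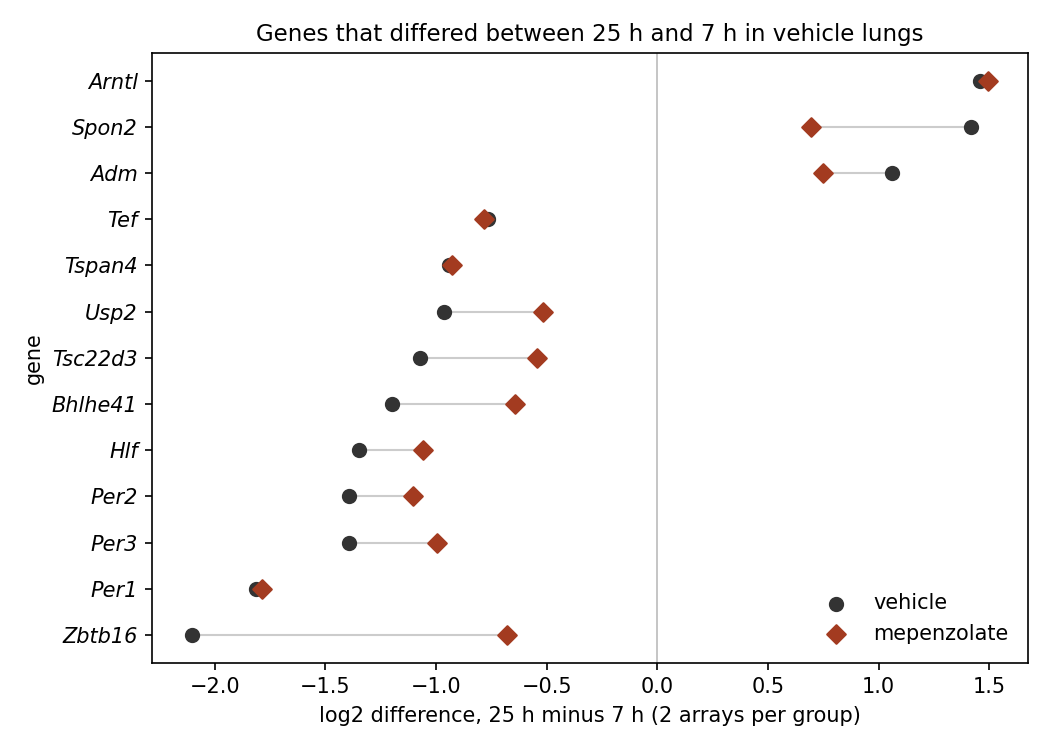
Log2 difference between 25 h and 7 h of the 13 genes that passed in vehicle lungs (dark circles), beside the same difference in mepenzolate lungs (red diamonds), from 2 arrays per group. Zbtb16 stands at -2.10 in vehicle and -0.68 in mepenzolate lungs, and Arntl at 1.46 and 1.49.

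Glucocorticoid genes fell as a list in vehicle lungs between 7 h and 25 h, in 18 of 19 cases (mean -0.64, camera adjusted p = 1.36e-23), with adjusted p = 0.0858 with an estimated correlation and 0.0156 with fry. Clock genes and their outputs were lower in 17 of 21 cases (mean -0.68, camera adjusted p = 1.72e-20), and adjusted p = 0.193 with an estimated correlation. Proliferation genes were higher in 28 of 32 cases (mean 0.23, camera adjusted p = 5.85e-14), with Mki67 at 0.55 ± 0.09 and Top2a at 0.43 ± 0.10, and adjusted p = 0.256 with an estimated correlation. Adjusted over the list alone, 14 glucocorticoid genes were lower, 2 clock genes higher and 15 lower, and 8 proliferation genes higher. Per1 is in both of the first 2 lists, and leaving it out kept both calls.

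Lymphoid and dendritic cell markers were higher as lists at 25 h than at 7 h in vehicle lungs. T and NK cell genes were higher in 22 of 27 cases (mean 0.14, camera adjusted p = 4.32e-05), with Thy1 at 0.30 ± 0.08, and adjusted p = 0.173 with an estimated correlation. Dendritic cell genes were higher in 13 of 16 cases (mean 0.16, camera adjusted p = 0.00019), with Cd209a at 0.41 ± 0.10, and adjusted p = 0.185 with an estimated correlation. Plasma cell genes were higher in 9 of 11 cases (mean 0.20, camera adjusted p = 0.00284), with Igha at 0.74 ± 0.22, and adjusted p = 0.193 with an estimated correlation. B cell genes were higher in 21 of 22 cases (mean 0.38, camera adjusted p = 7.11e-10), and adjusted p = 0.538 with an estimated correlation. The B cell mean was 0.68 without the first vehicle array at 25 h and 0.09, no longer called, without the second. Adjusted over the list alone, 2 plasma cell genes and 0 of the other 3 lists passed limma. Igha stood at 0.43 without the second vehicle array at 25 h. The MHC class II list was also called, though its scores were -0.20 and 0.30 at 25 h and -0.01 and 0.08 at 7 h. With 1 array left out its mean difference ranged from -0.24 to 0.26. Only 8 of its genes were tested. Its member H2-Eb1, which had 2 separate levels over the arrays, stood at 7.66 and 10.03 at 25 h and at 9.87 and 10.22 at 7 h.

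Interferon response genes were lower in 21 of 28 cases (mean -0.11, camera adjusted p = 0.00246), with Oasl2 at -0.43 ± 0.11, and adjusted p = 0.538 with an estimated correlation. Cytochrome P450 genes were lower in 16 of 20 cases (mean -0.16, camera adjusted p = 0.000103), with Sult1a1 at -0.59 ± 0.08, and adjusted p = 0.256 with an estimated correlation. Heat shock genes were lower in 16 of 18 cases (mean -0.12, camera adjusted p = 0.00654), with Hspb1 at -0.90 ± 0.14, and adjusted p = 0.538 with an estimated correlation. Limma passed 0 interferon genes, 1 cytochrome P450 list gene and 1 heat shock gene when adjusted over the list alone. Camera called 18 of 52 lists, 9 in each direction, against 0 with an estimated correlation, 1 with fry and 18 with fgsea. At an unadjusted p under 0.05 an estimated correlation and fry gave 8 lists each, and 9 of the 18 calls ended with at least 1 array left out.

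In mepenzolate lungs all 13 of the genes that changed in vehicle lungs moved in the same direction between 7 h and 25 h, and 11 of them by less. These genes were chosen by their change in vehicle lungs, which favours larger values there. Of the 13 genes with the smallest p in mepenzolate lungs, a count made after the data were seen, 10 changed by less in vehicle lungs. Zbtb16 stood at -0.68, Tsc22d3 at -0.54, Spon2 at 0.69, Bhlhe41 at -0.64 and Usp2 at -0.52, while Arntl (1.49) and Tef (-0.78) moved slightly more than in vehicle lungs. Per1 stood at -1.79, Per2 at -1.11, Hlf at -1.06, Tspan4 at -0.93 and Adm at 0.75. The gene-level test of the difference between times, which is the same contrast, passed for 0 of these genes.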

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

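The tests on clock genes and on leaving out the second mepenzolate array at 7 h were chosen after the result was seen, and the second of these was changed to compare the same genes in pairs after a first form with an unpaired error. The tests on further liver and airway genes replaced earlier ones on the lists that had shown the pattern. Their genes and bounds were fixed before those genes were looked at, but the requirement that the exact interval clear the bounds was added after their results were seen.

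The effect of mepenzolate differed between 25 h and 7 h for 21 gene lists by camera's test of that difference, at the preset correlation. Estimated correlations left 0 of them (adjusted p = 0.396 to 0.769), fry called 0 (smallest adjusted p = 0.503) and fgsea called 17. At an unadjusted p under 0.05 an estimated correlation gave 5 lists and fry 3. In mean log2, 25 h minus 7 h, the differences were 0.37 for club cells, 0.30 for glucocorticoid response, 0.29 for platelets, 0.27 for cytochrome P450, 0.25 for ciliated cells, 0.19 for thymocytes and for cardiac muscle, and 0.17 for glutathione S-transferases. They were 0.14 for B cells, 0.12 for respiratory chain and for ribosomal genes, 0.11 for NRF2 targets, 0.085 for p53 targets and 0.067 for the proteasome. They were -0.36 for liver, -0.21 for inflammatory cytokines, -0.19 for proliferation and for neutrophils, -0.15 for plasma cells, -0.085 for endothelial cells and -0.087 for NADPH oxidase subunits. With 1 array left out in turn, 7 of the 21 calls held each time. Without the second mepenzolate array at 7 h the calls ended for ciliated cells (-0.0022), liver (-0.075), NRF2 targets (0.043), p53 targets (0.062), plasma cells (-0.11) and the proteasome (-0.0083), with cardiac muscle at 0.30, club cells at 0.10, endothelial cells at -0.15 and glutathione S-transferases at 0.11. For B cells (0.11), cardiac muscle (0.076), endothelial cells (-0.025), NADPH oxidase (-0.063), p53 targets (0.11), plasma cells (-0.19) and thymocytes (0.16) the calls ended without the first mepenzolate array at 7 h, with ciliated cells at 0.51, club cells at 0.65, liver at -0.65, NRF2 targets at 0.18 and the proteasome at 0.14. Without the first mepenzolate array at 25 h the calls ended for cardiac muscle (0.019), endothelial cells (-0.069), liver (-0.35), NADPH oxidase (-0.057), neutrophils (-0.19), p53 targets (0.045) and plasma cells (-0.14), with B cells at 0.23, ciliated cells at 0.15 and ribosomal genes at 0.22. For B cells (0.046), ribosomal genes (0.031), cytokines (-0.14), liver (-0.37), plasma cells (-0.16), the proteasome (0.060) and thymocytes (0.16) the calls ended without the second mepenzolate array at 25 h, with cardiac muscle at 0.35. Without the first vehicle array at 25 h the calls ended for B cells (-0.16), cardiac muscle (-0.0025), neutrophils (-0.081) and thymocytes (0.11), with endothelial cells at -0.13 and proliferation at -0.12. For ciliated cells (0.15), endothelial cells (-0.039), liver (-0.30), NADPH oxidase (-0.071), NRF2 targets (0.068), p53 targets (0.084), plasma cells (-0.090) and the proteasome (0.065) the calls ended without the second vehicle array at 25 h, with B cells at 0.44, cardiac muscle at 0.38 and neutrophils at -0.30. Without the first vehicle array at 7 h the calls ended for B cells (0.024), liver (-0.27), NADPH oxidase (-0.046), p53 targets (0.056) and the proteasome (0.055), with neutrophils at -0.32. For cardiac muscle (0.17), endothelial cells (-0.049), neutrophils (-0.065) and plasma cells (-0.14) the calls ended without the second vehicle array at 7 h, with B cells at 0.26.

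Glucocorticoid response genes were lower under mepenzolate at 7 h (mean -0.28), a time at which vehicle lungs had high levels of them. Sampling at another time of day is argued against only as a shift that moves clock genes as far as glucocorticoid genes. At 7 h 20 clock genes without Per1 had a median absolute log2 difference of 0.070 (bootstrap 95% interval over genes 0.048 to 0.096). It was 0.251 (0.185 to 0.381) for 18 glucocorticoid genes, a list picked for its shift in these data, and 0.059 for all genes. Such intervals over genes do not measure the spread between arrays. The score of the whole clock list was 0.26 and 0.28 on the mepenzolate arrays, against 0.30 and 0.40 on the vehicle arrays. A smaller offset in sampling time is therefore not excluded. The make-up of the second mepenzolate array at 7 h is argued against as the cause of most of the shift: without it the mean was -0.30, which is 104% of the full shift (bootstrap 95% interval over genes 60.7 to 125). A lower glucocorticoid signal in mepenzolate-treated mice may account for the pattern and stays open as an untested hypothesis, as does a difference in handling stress between the groups. No corticosterone level was used here, and the list's call was lost with an estimated correlation (adjusted p = 0.265).

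The second mepenzolate array at 7 h had 9 of 13 listed liver genes at their highest, 12 of 20 club cell genes and 21 of 26 ciliated cell genes at their lowest among the 8 arrays. Liver RNA in that sample may be a source of the high genes. Of 18 further liver genes, however, 2 were highest there (11.1%, exact 95% interval 1.38 to 34.7, chance 12.5%). That interval lies under the upper bound but not under the lower one, so this stays open. Most of the 18 are dim in lung, but those 2, Serpinc1 and Apob, were below the filter level themselves. So were the listed Cps1, Apoc3, Fgb, Ambp and Ttr, highest there, and Apoh, which was not. The brighter further genes Vtn, Itih1, Itih2, Itih3, Bhmt, Apoc4 and F2 were not highest there. Albumin, Alb, stood at 8.93 on that array against a mean of 6.21 elsewhere and Apoa1 at 7.36 against 6.68, while Vtn stood at 8.01 on both sides. The listed gene Fabp1 was lower there, at 6.58 against 7.14, and Cyp2e1 stood at 8.76, below the 9.27 of another array. Less conducting airway in that sample may account for the low genes: 30 of 34 further ciliated genes were lowest there (88.2%, interval 72.5 to 96.7), but only 3 of 8 further club genes (37.5%, 8.52 to 75.5), and 8 genes are too few to decide. An effect of mepenzolate in the sample of 1 of its 2 arrays at 7 h is a biological alternative that 2 arrays cannot separate from these.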

How the results depend on the processing

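The alternatives here were planned, except the fits without Per1, chosen after seeing the data. Estimated correlations gave 0 lists in each of the 5 comparisons, and fry 0, 0, 0, 0 and 1, against 11 (25 h), 26 (7 h), 9 (both times), 21 (difference) and 18 (vehicle time course). Of the 85 list calls fgsea kept 68, no filter 72 and quantile normalization 68, and at 25 h quantile normalization gave 6 lists. The cause of the other changes was not tested. For the 13 genes of 25 h against 7 h in vehicle mice, quantile normalization gave 7 (2 higher, 5 lower), an intensity trend with robust estimation 33 (6 and 27) and array weights 55 (14 and 41). All 13 were among the last 2 sets and 7 among the first. A fit on the vehicle arrays alone gave 11 calls, 7 of them among the 13. A stricter filter gave 17, with 11 of the 13, and left the other 2, Arntl and Bhlhe41, untested. Without Per1 the list counts stayed at 26 (7 h) and 18.

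With the replicate number as a block, limma called 1, 0, 0, 0 and 17 genes in the order above, against 0, 0, 0, 0 and 13, and camera 9, 23, 9, 21 and 17 lists. The 8 list calls it ended (adjusted p = 0.0512 to 0.0723) were NRF2 targets and proliferation at 25 h, ribosomal genes, NADPH oxidase, T and NK cells and interferon response at 7 h, NADPH oxidase in the difference and club cells in the vehicle time course. The numbers were not taken to pair the arrays, as deviations of same-numbered arrays correlated at -0.02 to 0.40 across genes and exceeded 0.1 in 3 of 6 pairs of groups.

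Leaving out 1 array at a time gave 0 to 1 genes at 25 h, 0 to 2 at 7 h, over both times and for the difference, and 0 to 14 in the vehicle time course. It gave 7 to 19, 10 to 28, 8 to 16, 13 to 24 and 14 to 24 lists, from fewer samples. At 25 h log2 differences that changed sign ranged from -0.0069 to 0.49 for Aox1, -0.15 to 0.085 for Chrm1, -0.12 to 0.11 for Eln, -0.11 to 0.017 for Mmp12, -0.033 to 0.13 for Nfkbia, -0.039 to 0.061 for Sod1, -0.18 to 0.13 for Sod3 and -0.085 to 0.14 for Tnf. At 7 h they ranged from -0.16 to 0.65 for Apoa1, -0.14 to 0.57 for Apoa2, -0.81 to 0.063 for Ccdc39, -0.018 to 0.27 for Mmp12, -0.025 to 0.064 for Hdac2, -0.16 to 0.040 for Sod1, -0.14 to 0.22 for Cybb, -0.014 to 0.080 for Ncf1, -0.0034 to 0.026 for Nfe2l2, -0.063 to 0.28 for Tnf, -0.0011 to 0.19 for Cxcl1, -0.12 to 0.0043 for Chrm1, -0.18 to 0.067 for Chrm2, -0.51 to 0.25 for Chrm3, -0.14 to 0.29 for Eln, -0.50 to 0.019 for Perp and -0.074 to 0.35 for Rpl14. List means ranged at 7 h from -0.43 to 0.078 for ciliated cells, -0.00047 to 0.094 for interferon response, -0.080 to 0.17 for neutrophils, -0.13 to 0.0021 for NRF2 targets, -0.011 to 0.087 for alveolar type 1 cells and -0.0058 to 0.083 for heat shock. MHC class II ranged from -0.24 to 0.26 in the vehicle time course, and interferon response from -0.0065 to 0.075 over both times. They ranged from -0.15 to -0.019 for proliferation at 25 h, where camera's direction turned, and from -0.16 to 0.44 for B cells in the difference. At 25 h Sod1 turned to -0.013 under quantile normalization, and Sod3, Cybb and Eln to 0.0033, 0.016 and 0.020 under median centring. The pseudocount alternative was not run, since the values were already log2. Differences of genes near background are compressed by array summaries, which limits what dim genes can show.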

Other observations

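The tests on splits of the arrays and on genes with 2 separate levels were chosen after the results were seen, and the split fit was changed to the form of the reported comparison after a first run with split and time as added terms.

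Neutrophil genes were higher at 25 h than at 7 h in vehicle lungs, in 13 of 17 cases (mean 0.16, camera adjusted p = 0.00654), and adjusted p = 0.627 with an estimated correlation. S100a8 and S100a9, subunits of calprotectin, stood at 0.95 ± 0.17 and 0.62 ± 0.16, and these 2 genes passed when adjusted over the list alone. The call ended without the first vehicle array at 25 h (0.05) and without the second at 7 h (0.03), and the mean was 0.27 without the second at 25 h and 0.29 without the first at 7 h. Among immediate early genes, Ccn2, a matricellular growth factor, stood at -0.64 ± 0.11 and the nuclear receptor Nr4a2 at -0.56 ± 0.15. That list was lower in 16 of 26 cases (mean -0.09, camera adjusted p = 0.0203), and adjusted p = 0.534 with an estimated correlation. Its call ended without the second vehicle array at 7 h (-0.06), and S100a9 stood at 0.40 without the same array.

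Genes that stood at a high level in some samples and a low level in others followed neither time nor treatment in 8 of 10 cases, taking a gap of at least 1 log2 unit between 2 sets of at least 2 arrays. H2-Ea, a class II histocompatibility gene, stood at 11.57 in the second vehicle arrays at 7 h and 25 h and at 6.69 in the other 6 arrays. A single array batch is argued against as the source of these gaps. The commonest split of the arrays held 25% of the 8 genes, which fell into 6 splits. A batch that shifts many genes slightly would not show in such gaps. Genetic differences between the mice may be the source, as H2-Ea shares its split with its neighbour D17H6S56E-5, but this was 1 of 3 neighbouring pairs (gene order from GRCm38.p6), and the permutation p of 0.221 is the smallest these pairs can give. The other genes were H2-Eb1, Ang5, Baiap2l1, Ctse, and Cwc22 with Fam171b, which share a split, and no biological explanation was tested with genotypes.

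Of the 35 ways to split the 8 arrays 4 against 4, 18 gave at least as many genes at an unadjusted p under 0.05 as mepenzolate against vehicle (563, highest other 2801), so chance cannot be excluded for that count. For gene lists 25 splits gave at least as many as the real 9 (highest other 23), and chance cannot be excluded there either. The split by time gave 1497 genes and 20 lists, and the split by replicate number 1960 genes and 11 lists. The 12 lists called between replicate numbers above came from another fit, with a mean per group and the replicate number added. Splits that call several times the real count may reflect a structure of the samples. The split with 2801 genes set the 4 arrays with the lowest median values against the other 4. These were the first mepenzolate array at each time and both vehicle arrays at 7 h. The splits of all 8 arrays by time and by replicate number did not set these 4 apart. The vehicle time course did run along this split, as both of its arrays at 7 h were among the 4 and both at 25 h were not. With median centring limma called 19 genes in that comparison, among them all 13 called without it. Median centring was not run for its lists, so an effect of the array medians on those calls is not excluded. Whether the array medians or something else gave the high counts was not tested. With added terms the real count was 620 genes (18 splits, highest other 2901) and 9 lists (25 splits, highest other 24).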
